A study of Homo sapiens with 8 samples.

How the data were processed

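RNA was measured in 8 samples of MDA-MB-231 cells, 2 per group. Per the labels' protocols, the compounds were added at 20 µM at seeding and renewed daily, total RNA was extracted with Trizol after 48 h, and BGI Americas prepared and sequenced the libraries and analysed the data. The submitters' processing notes name HISAT, StringTie, Bowtie, RSEM and DESeq2 and the genome builds GRCh38, hg38 and mm10, with no version, role or order. The gene symbols are human. Whether the libraries were stranded or selected for poly(A) RNA is not given in the sources used here, so genes that overlap on opposite strands cannot be separated.

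Each of the 3 deposited tables compares 1 compound with untreated cells. Per the file headers, the authors give the mean FPKM of each group, a log2 fold change and a q-value per gene, with gene ID and symbol. FPKM values move in steps of 0.005 and none is under 0.01, so 0.01 was read as the lowest value listed. The deposited log2 fold changes are treated over untreated, by comparison of their sign with the FPKM means. The deposited q-values are all under 0.05 and the absolute log2 fold changes all at least 0.5, which are therefore the apparent criteria. No column held values per sample, so no replicate was compared, no standard deviation is given and no count model was fitted. The depth is unknown, and a low FPKM cannot be turned into a number of reads. The tables hold no unadjusted p-values and no genes that missed the criteria, so no count adjusted over the list alone could be made. The authors' untreated FPKM means were equal in all tables for the shared genes.

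The standard error of each fold change was taken as its absolute value divided by the normal quantile of the q-value used as a two-sided p-value. A Benjamini-Hochberg q-value is at least as large as its p-value, so this bounds the error from above, if the authors' test was a Wald test on unshrunken fold changes. A q-value listed at 0 (7 genes for brazilin, 2 for acetylated brazilin) was taken as 1e-300. As a check on shrinkage, the log2 fold change was divided by the log2 ratio of FPKM means. For brazilin the median was 0.97 in genes above 0.01 and under 1 FPKM in both groups. It was 1.09 in genes with at least 10 FPKM. The brazilin fold changes lie a median of 0.09 below that ratio, which raises the quotient for falls and lowers it for rises. The brazilin values therefore cannot decide on shrinkage. For acetylated brazilin the medians were 0.99 (10 genes) and 1.01 (85 genes). The difference between compounds was the difference of the fold changes over the root of the summed squared errors, two-sided, with Benjamini-Hochberg adjustment over the genes a pair of tables shares. Shared controls make that error too large. Before the data were examined the plan was to set fold changes side by side if the tables gave no p-value, and the use of q-values was added afterwards.

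Fixed before the data were examined were 32 gene lists with 853 entries, of which 836 matched a gene ID in the RefSeq table of GRCh38.p14, through current symbols or synonyms. For each list with at least 5 members in a table, the numbers higher and lower were compared with those of the other listed genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists tested (19 for brazilin, 1 for acetylated brazilin). This tests direction within a table, not enrichment. The lists overlap in part with each other.

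Genes named in the text followed a rule fixed beforehand. In a table of at most 30 genes every gene is named. In the others these are the 8 largest rises and the 8 largest falls among genes with at least 1 FPKM in the higher group, the 3 members with the smallest q-value of each list with at least 5 members, and the 10 genes in 2 or 3 tables with the largest change with brazilin. Genes outside the rule are marked as named after their values were seen.

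Transcript length and GC content came from the GENCODE release 29 transcripts, matched for 2870 of 2885 brazilin genes (99.5%), taking 1 transcript per gene. Near-identical copies were searched with BLAST+ 2.17.0 between coding sequences, at a minimum identity of 98% over at least 80% of the length. The 97 brazilin genes and 24 acetylated brazilin genes with such a copy are uncertain, since the authors' counting may divide reads between copies. Positions are those of the RefSeq table. Overlap between tables was set beside simulated comparisons that share their controls and beside the number expected of independent lists, for which the number of genes tested had to be assumed.

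Other settings chosen beforehand were q-value thresholds of 0.01 and 0.001, log2 thresholds of 1 and 2, a minimum of 1 FPKM, matching on symbols, a covariance for the shared controls, lists without genes that stand in more than 1 list, and the mean of both groups as abundance. Added after the data were seen were the q-based error, the ratio of FPKM means as the fold change, and list tests within 10 classes of transcript length, within 5 classes each of length and GC content, within 10 classes of mean FPKM and without genes that have near-identical copies.

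The procedures were tested on simulated data. For brazilin against untreated cells, with the 2885 listed genes, 3.15% of 2000 random lists of 15 genes had p under 0.05 (2.75% for the test within strata). Lists of 15 with 75% of members higher were recovered in 46.0% of cases and those with 90% higher in 95.0%. For brazilin against acetylated brazilin, with 15000 simulated genes, the 95% intervals covered the true fold change in 94.2% of genes listed for the simulated brazilin. There, 0.0177% of equal effects were called different, and 95.1% of effects that differed by over 1 were called different. Both simulated compounds changed the same large set of genes, whereas the real acetylated brazilin table lists 193. Its q-values may lie further above their p-values, so these rates may not hold for the real comparison. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.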

Results

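Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established line from a triple-negative human breast cancer, after exposure to brazilin or to a methylated or acetylated derivative of it. Brazilin is the phenolic compound from which the red dye of sappanwood and brazilwood is formed. The 8 samples fell into 4 groups of 2, which were untreated cells, cells given unmodified brazilin, cells given methylated brazilin and cells given acetylated brazilin. Each compound was used at 20 µM for 48 h, with the first addition at seeding and daily renewal. Whether the untreated cells received solvent is not given in the sources used here. The 3 deposited tables list, for each compound against untreated cells, the genes that the authors called significant, with the mean FPKM of both groups, a log2 fold change and a q-value. They hold no values per sample and no read totals, so the depth is unknown and the spread between replicates cannot be seen directly. Nothing in the labels says that the 2 samples of a group came from separate cultures, so the q-values measure only the spread between these samples, which may be technical. Intervals given in this text are 95% intervals from a standard error that was derived from the authors' q-value, an upper bound for the error if the authors' test was an unshrunken Wald test. Unless another source is named, each FPKM, log2 fold change and q-value of a gene is that of the authors' deposited table for the compound named.

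The first comparison asked which genes changed with unmodified brazilin. The authors' deposited table lists 2885 genes, of which 1374 were higher and 1511 were lower than in untreated cells. HMOX1, the inducible heme oxygenase that breaks heme down to iron, biliverdin and carbon monoxide, rose from 11.4 to 516 FPKM, a 42.5-fold change (log2 5.41, interval 5.12 to 5.70). The transcription factor genes EGR1 and EGR2 rose by 3.18 (interval 3.01 to 3.35) and 4.65 (3.77 to 5.52) on the log2 scale, EGR1 to 125 FPKM. The largest falls among genes with at least 10 FPKM in the higher group were those of ITGA1, the integrin alpha 1 chain (34.2 to 5.75 FPKM, log2 -2.67, interval -2.81 to -2.53), AGR2, an endoplasmic reticulum protein of the disulfide isomerase family (171 to 31.4 FPKM, log2 -2.53, interval -2.66 to -2.39), and the transcription factor gene SOX4 (31.5 to 7.30 FPKM, log2 -2.20, interval -2.33 to -2.07). Large changes were mostly rises. With brazilin 533 genes were at least 2-fold higher and 277 at least 2-fold lower, and at 4-fold or more the counts were 203 and 22. However, 50 listed genes stood at the lowest value of 0.01 FPKM in untreated cells, against 5 with brazilin. Some of the largest rises therefore rest on that value. The authors' fold changes sit below the ratios of their own FPKM means by a median of 0.09 on the log2 scale in this table, so the split depends on the scaling. By the ratio of FPKM means, with the same minimum of 0.5 on the log2 scale, 1371 of the listed genes were higher and 977 lower, or 58.4% higher against 47.6% as deposited. Genes that would pass only by this ratio are absent, so the 58.4% holds for listed genes alone.

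Several other genes with large changes were under 5 FPKM in both groups. With brazilin IFNL1, an interferon lambda gene, went from 0.05 to 3.32 FPKM, ARL14, a small GTPase gene, from 0.075 to 2.02 FPKM, and the histone gene H2BC6 from 0.065 to 3.66 FPKM in the authors' deposited table. CFI, which encodes complement factor I and has a near-identical copy, fell from 1.27 to 0.185 FPKM, VIP, a neuropeptide gene, from 1.40 to 0.255 FPKM, and OLAH, a thioesterase gene of fatty acid synthesis, from 4.03 to 0.765 FPKM. HBA1, an alpha globin gene, was listed at 0.01 FPKM, the lowest value in the tables, in untreated cells and at 4.12 FPKM with brazilin, while its copy HBA2, with an identical coding sequence, was listed at 0.76 and 0.01 FPKM. P2RY11, a nucleotide receptor gene, was listed at 1.89 FPKM in untreated cells and at 0.01 FPKM with brazilin, and its coding sequence is shared with the readthrough gene PPAN-P2RY11. Genes with such copies are uncertain, because reads can be assigned to either member. MTRNR2L8, a far more abundant transcript and one of a set of nuclear genes that resemble the mitochondrial 16S ribosomal RNA gene, fell from 2819 to 668 FPKM (log2 -2.16, interval -2.28 to -2.04), and it is uncertain for the same reason.

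The fixed list of replication-dependent histone genes has 51 members, of which 18 were listed with brazilin, all 18 higher than in untreated cells. These genes encode the histones made during DNA replication, and their median log2 fold change was 3.14. H2BC12 rose from 63.7 to 414 FPKM (log2 2.52, interval 2.39 to 2.66), H2BC4 from 3.58 to 96.4 FPKM (log2 4.39, interval 4.11 to 4.68) and H2BC21 from 1.98 to 21.2 FPKM (log2 3.33, interval 3.09 to 3.58), while H2BC3 was listed at 0.01 FPKM in untreated cells and at 1.94 FPKM with brazilin. Against the other listed genes the histone list was tilted towards higher values (two-sided Fisher's exact test, adjusted p = 2.85e-05 over 19 lists, and 0.0156 within 10 classes of transcript length). H2BC12 has a near-identical copy in H2BFS, and without genes that have such a copy 17 of 17 were higher. Of the 43 DNA replication and G1/S genes fixed beforehand, 3 were in the table, MCM5, CDC25A and GINS2, which were higher by 0.54 to 0.56 and were named after their values were seen. Ribosome biogenesis had 10 of 23 fixed genes listed, all of them also higher (median log2 0.80, Fisher's exact test, adjusted p = 0.00374). BOP1 rose from 38.5 to 85.1 FPKM, RRP9 from 22.2 to 49.1 FPKM and NOP2 from 38.9 to 73.4 FPKM. Short and GC-rich transcripts were more often higher in this table, and the ribosome biogenesis call was lost within classes of both transcript length and GC content (adjusted p = 0.0997, range over its settings 0.00164 to 0.0997), a setting chosen after the data were seen.

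Of 45 fixed genes of mitosis and G2/M 17 were listed with brazilin, 16 of them lower (median log2 -0.66, two-sided Fisher's exact test, adjusted p = 0.00314). ASPM, a spindle pole protein gene, fell from 19.8 to 8.90 FPKM (log2 -1.30, interval -1.42 to -1.19), CENPF, a kinetochore protein gene, from 36.5 to 18.5 FPKM (log2 -1.09, interval -1.20 to -0.98), and TOP2A, the gene of DNA topoisomerase II alpha, from 78.2 to 42.8 FPKM (log2 -0.95, interval -1.05 to -0.86) in the authors' deposited table. The exception was CKS2, at 220 and 326 FPKM, named after its value was seen. The integrated stress and unfolded protein response had 16 of 30 fixed genes listed, 14 of them lower (median log2 -0.75, Fisher's exact test, adjusted p = 0.0149). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 2379 to 1230 FPKM (log2 -1.04, interval -1.13 to -0.96), and HSP90B1, its HSP90 family chaperone, from 1243 to 561 FPKM (log2 -1.24, interval -1.33 to -1.15). ATF3, a stress-induced transcription factor gene of the same list, rose from 29.8 to 128 FPKM (log2 2.01, interval 1.88 to 2.14), and STC2, the other exception and also named after its value was seen, from 0.59 to 1.19 FPKM. Among members that changed by at least 1 on the log2 scale, 5 of 6 were lower and the call was lost (adjusted p = 0.0591, range over its settings 0.00189 to 0.0591).

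Hypoxia and glycolysis genes and lipid synthesis genes were lower without exception among the listed members. These were 11 of 32 and 9 of 31 fixed genes, and the others have no values here. All 11 listed hypoxia and glycolysis genes fell (median log2 -0.71, two-sided Fisher's exact test, adjusted p = 0.00513), among them NDRG1 from 260 to 132 FPKM, VEGFA, the vascular growth factor gene, from 123 to 72.0 FPKM and P4HA1, a collagen prolyl hydroxylase gene, from 65.2 to 37.7 FPKM. All 9 listed cholesterol and fatty acid synthesis genes fell (median log2 -0.72, adjusted p = 0.0149), with SCD, the stearoyl-CoA desaturase gene, going from 341 to 213 FPKM and the fatty acid desaturase genes FADS1 and FADS2, from 118 and 177 FPKM, lower by 0.75 each on the log2 scale. Of the brazilin genes in the longest of 5 classes of transcript length 19.2% were higher, against 82.8% in the shortest. Within 10 classes of transcript length the lists of mitosis, stress response and hypoxia each had an adjusted p of 0.00189, and the lipid list one of 0.0128. The test asks only whether a list's direction differs from that of the other listed genes, and genes are not independent replicates, so these p-values describe the table.

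**Figure D1:**
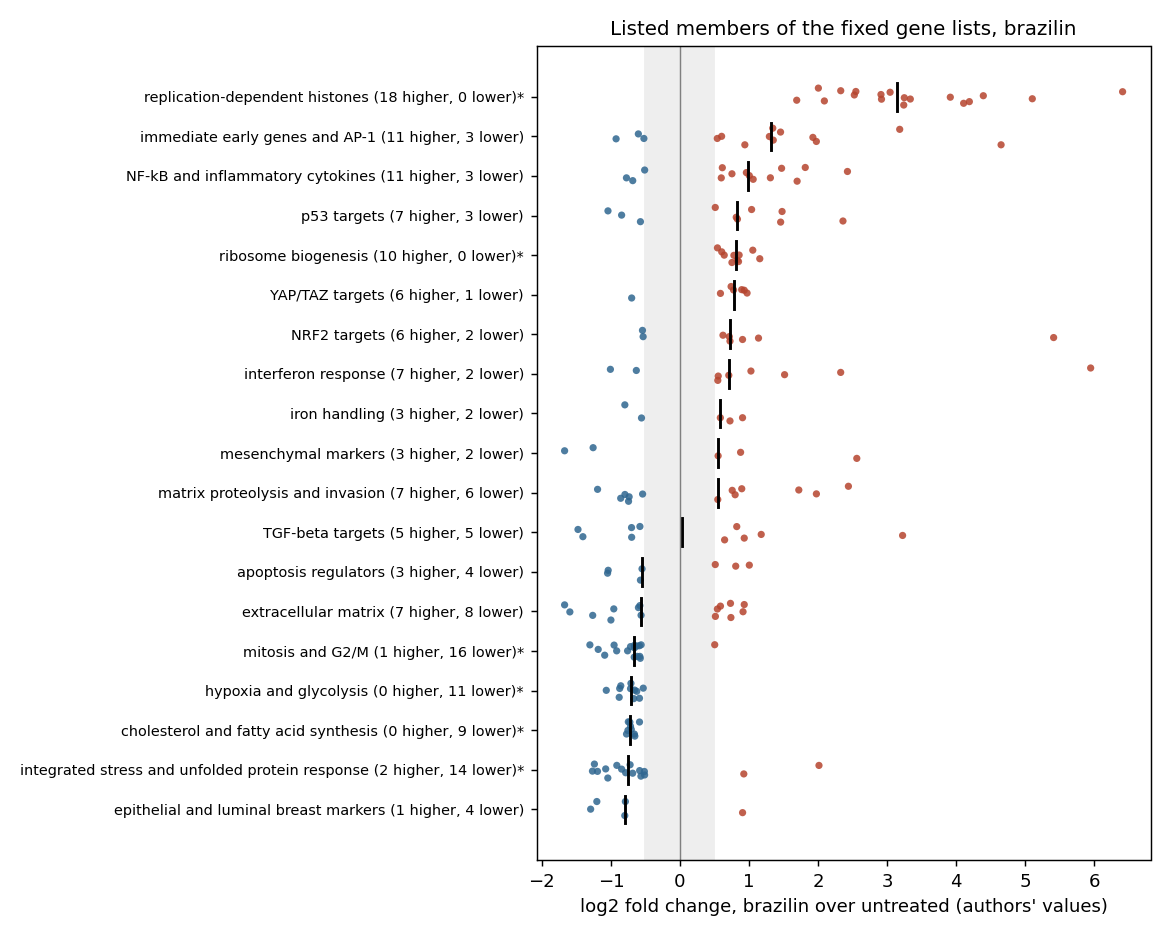
Log2 fold change, brazilin over untreated, of each listed member of the 19 fixed gene lists with at least 5 members in the authors' deposited table. Points are genes, red if higher and blue if lower, black bars are list medians, the grey band spans changes under 0.5 that the table does not list, and an asterisk marks an adjusted p under 0.05. All 18 histone genes lie to the right, and the 11 hypoxia and 9 lipid synthesis genes lie to the left.

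Listed inflammatory and immediate early genes were mostly higher with brazilin, but their lists were not past the threshold among all listed genes. Both passed among genes with q under 0.001 (adjusted p = 0.0402 and 0.0479) and among genes with at least 1 FPKM in the higher group (0.0297 and 0.0464), over ranges of 0.0297 to 0.296 and 0.0464 to 0.173. Of 14 listed genes of NF-kB and inflammatory cytokines 11 were higher (adjusted p = 0.0686), including TNFAIP3, a feedback inhibitor of NF-kB (4.42 to 15.3 FPKM), and the cytokine genes IL24 (9.45 to 34.7 FPKM) and IL6 (167 to 346 FPKM). Immediate early and AP-1 genes gave 11 higher and 3 lower (adjusted p = 0.0686), with JUN at 47.0 and 128 FPKM and IER2 at 46.9 and 127 FPKM. Of the NRF2 targets, the antioxidant and iron storage genes of that transcription factor, 6 of 8 were higher (adjusted p = 0.280), with HMOX1 as above, GCLM, the modifier subunit of glutathione's first synthesis enzyme, at 13.3 and 31.2 FPKM (log2 1.14, interval 1.01 to 1.26) and FTH1, the ferritin heavy chain gene, at 2929 and 5819 FPKM (log2 0.91, interval 0.82 to 0.99). SLC7A11, a cystine transporter gene of this list named after its values were seen, has a log2 fold change of -0.54 but FPKM means of 49.1 and 51.8. The 2 measures thus differ in direction, by more than the median scaling offset of 0.09 in this table. Its direction is uncertain, and the cause of the mismatch was not tested. The p53 targets gave 7 of 10 higher (adjusted p = 0.330), with GADD45A at 37.6 and 110 FPKM, GADD45B at 26.3 and 77.8 FPKM and PLK2 higher by 1.04 on the log2 scale. The interferon response gave 7 of 9 higher (adjusted p = 0.181), RSAD2 being higher at 1.76 and 3.83 FPKM and XAF1 and DDX58 lower by 1.01 and 0.63 on the log2 scale. YAP/TAZ targets gave 6 of 7 higher (adjusted p = 0.124), with CCN2 at 46.4 and 94.1 FPKM and F3, the tissue factor gene, at 53.8 and 106 FPKM.

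Genes of the matrix, of cell identity and of cell death went both ways with brazilin. FN1, the fibronectin gene, fell from 356 to 119 FPKM (log2 -1.67, interval -1.77 to -1.57) and LAMA3, a laminin gene, from 11.6 to 4.90 FPKM, while THBS1, the thrombospondin 1 gene, rose from 96.5 to 193 FPKM in the authors' deposited table, and the extracellular matrix list held 7 higher and 8 lower genes (adjusted p = 1). Matrix proteolysis and invasion gave 7 higher and 6 lower (adjusted p = 0.930), with TIMP3 and ADAM19 lower by 0.86 and 1.19 and CTSL higher by 0.89 on the log2 scale. The mesenchymal markers gave 3 higher and 2 lower (adjusted p = 0.854), SNAI1 rising from 1.37 to 8.60 FPKM and CDH11 falling from 57.1 to 25.6 FPKM. Of the epithelial and luminal markers 1 was higher and 4 were lower (adjusted p = 0.552), the tight junction genes CLDN7 and OCLN falling, CLDN7 from 34.70 to 15.995 FPKM and OCLN by 0.80 on the log2 scale, and ESRP2 rising by 0.91. TGF-beta targets split into 5 and 5 (adjusted p = 1), with PMEPA1 and LTBP1 lower by 1.48 and 1.41. Apoptosis regulators gave 3 higher and 4 lower (adjusted p = 1), BIRC3 being higher by 1.00 and BMF and TNFRSF10B lower by 1.04 and 0.57. Iron handling gave 3 higher and 2 lower (adjusted p = 0.854), with FTL, the ferritin light chain gene, at 3662 and 6385 FPKM and CYBRD1, an iron reductase gene, at 29.9 and 18.3 FPKM.

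The remaining lists had fewer than 5 members in the brazilin table and were not tested. The 4 listed aryl hydrocarbon receptor targets and the 4 listed genes of glutathione and drug metabolism, which share 2 genes, were all higher. CYP1A1, which both lists hold and which was named after its value was seen, went from 0.74 to 3.52 FPKM. Other lists gave 2 higher genes for heat shock, 1 higher for metallothioneins, 3 higher for nuclear oxidative phosphorylation, 1 higher and 3 lower for DNA repair, 1 higher and 2 lower for autophagy and lysosome, and 1 higher and 3 lower for chromatin enzymes. Markers of other cell types gave 3 higher and 1 lower for leukocytes and 2 higher and 1 lower for endothelium and fat. No member of the fixed lists of ribosomal protein genes and mitochondrially encoded genes was found in the table, although only 1 of the 15 mitochondrial symbols matched a gene ID.

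The second comparison asked which genes changed with acetylated brazilin. The authors' deposited table lists 193 genes, 120 of them higher and 73 lower, and 13 and 11 of them changed at least 2-fold. HMOX1 rose from 11.4 to 424 FPKM, a 37.0-fold change (log2 5.21, interval 4.93 to 5.48). FTH1 rose from 2929 to 8725 FPKM (log2 1.58, interval 1.49 to 1.66) and GCLM from 13.3 to 37.5 FPKM (log2 1.48, interval 1.35 to 1.61). The largest fall among genes with at least 1 FPKM in the higher group and no near-identical copy was that of DHRS3, a retinaldehyde reductase gene, from 36.6 to 12.2 FPKM (log2 -1.71, interval -1.89 to -1.53). The epithelial transcription factor gene ELF3 fell from 8.14 to 4.54 FPKM (log2 -1.08, interval -1.36 to -0.81) and the chemokine gene CCL26 from 37.9 to 17.1 FPKM (log2 -1.02, interval -1.43 to -0.62).

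NRF2 targets were the 1 fixed list with at least 5 members among the acetylated brazilin genes, and 8 of its 9 listed members were higher. Besides the genes named above, FTL, TKT, SLC48A1 and PIR rose by 0.56 to 0.75 on the log2 scale, and AKR1C1 was lower at 1.57 and 0.94 FPKM, all 5 named after their values were seen. The list was not past the threshold in the authors' deposited table (two-sided Fisher's exact test, adjusted p = 0.157). It passed among genes with q under 0.001, where 7 of 7 were higher (adjusted p = 0.0175), and without genes that have a near-identical copy, which leaves AKR1C1 out (adjusted p = 0.0274), with a range over its settings of 0.0175 to 0.274. HTRA3, a secreted serine protease gene, rose from 0.165 to 1.26 FPKM, ZFPM1, a transcription cofactor gene, from 1.15 to 2.45 FPKM, C10orf90 from 0.525 to 1.46 FPKM and OR7E24 from 0.41 to 1.09 FPKM. CFI, CDRT4 and MTRNR2L8 fell by 1.35, 1.07 and 0.98 on the log2 scale. The histone genes H4C12 and H4C11, whose coding sequences are identical, were listed in opposite directions, H4C12 at 0.01 and 3.42 FPKM and H4C11 at 3.57 and 0.01 FPKM in untreated and treated cells. MAGED4B, at 2.52 and 0.935 FPKM, also has an identical copy. Of the other fixed lists, iron handling had 2 genes, both also NRF2 targets, NF-kB and inflammatory cytokines had 1 higher and 2 lower, and epithelial markers had 1 of each. Mitosis, apoptosis, extracellular matrix, matrix proteolysis, TGF-beta targets and YAP/TAZ targets had 1 lower gene each. Of these TIMP3, an inhibitor of matrix proteases, was lower by 0.77. Replication-dependent histones had only H4C12 and H4C11, and the lists not named had none.

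The third comparison asked which genes changed with methylated brazilin, and the authors' deposited table lists 11 genes, 3 higher and 8 lower. NQO1, an NRF2 target that encodes a quinone reductase, rose from 100.5 to 156 FPKM (log2 0.63, interval 0.23 to 1.02), and BEST1, a chloride channel gene, from 1.92 to 6.05 FPKM (log2 1.64, interval 1.10 to 2.19). BEST1 overlaps FTH1, at 2929 FPKM in untreated cells, on chromosome 11, and reads of overlapping genes cannot be separated here, so its value is uncertain with either compound that lists it. TXNIP, the thioredoxin-interacting protein gene, fell from 224 to 119 FPKM (log2 -0.92, interval -1.31 to -0.53), CST1, the cystatin SN gene, from 130.2 to 66.9 FPKM (log2 -0.94, interval -1.31 to -0.56), and SOX4 from 31.5 to 18.9 FPKM (log2 -0.75, interval -1.06 to -0.44). CCL26 fell from 37.9 to 15.2 FPKM and GEM, a small GTPase gene, from 58.0 to 34.7 FPKM. TNFRSF9 and HSPA1A, a heat shock protein gene with a near-identical copy in HSPA1B, fell by 1.01 and 0.59 on the log2 scale, with q-values of 0.0481 and 0.0155. KRT34 was listed at 0.555 FPKM in untreated cells and 0.01 FPKM in treated cells, and SLX1B, whose copy is SLX1A, at 0.01 and 1.07 FPKM. No fixed list had 5 members in this table, NQO1 being the 1 listed NRF2 and aryl hydrocarbon receptor target and HSPA1A the 1 heat shock gene.

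**Figure D2:**
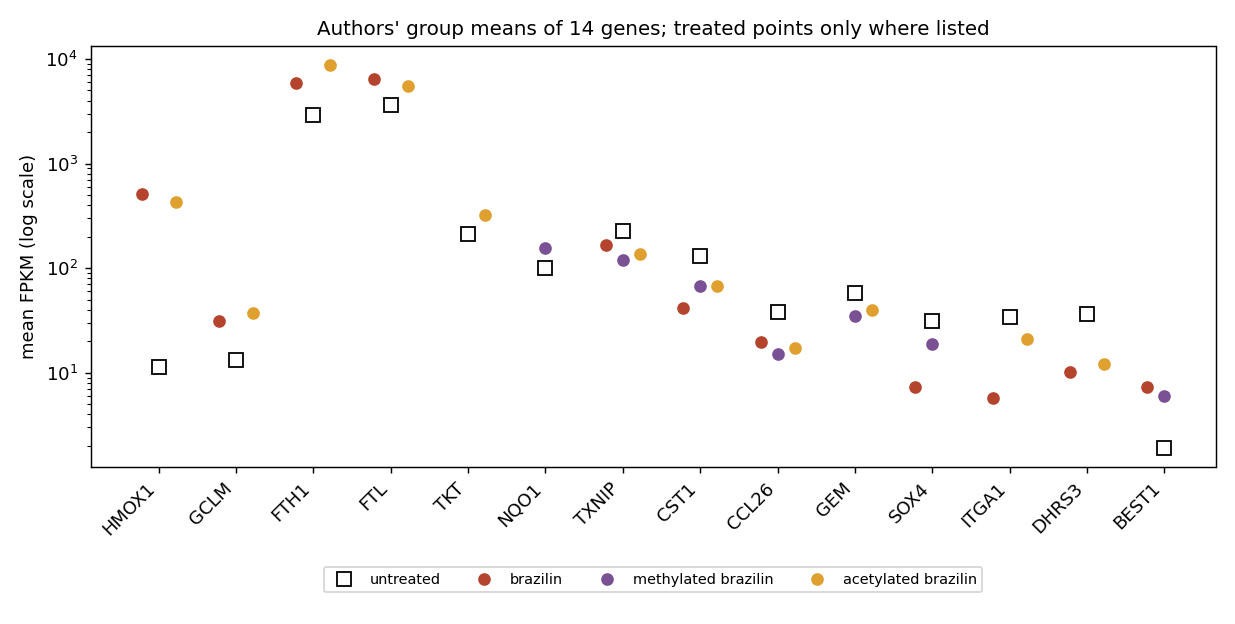
Authors' mean FPKM (log scale) of 14 genes in untreated cells (open squares) and, where the authors' deposited table for that compound lists the gene, in cells given brazilin, methylated brazilin or acetylated brazilin (filled circles). The genes were chosen after their values were seen, and the tables give no errors for these means. HMOX1 stands at 11.4 FPKM untreated and at 516 and 424 FPKM with brazilin and acetylated brazilin, and TXNIP, CST1 and CCL26 are below the untreated level with all 3 compounds.

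The compounds were compared at the same dose and time, through the genes that 2 tables share. Brazilin and acetylated brazilin shared 84 genes, of which 74 (88.1%) changed in the same direction, 28 higher and 46 lower with both. HMOX1 did not differ detectably between them, with a log2 difference of 0.20 (interval -0.20 to 0.60), nor did HTRA3 (0.27, interval -0.98 to 1.52) or DHRS3 (-0.25, interval -0.52 to 0.01). For 38 of the 84 genes the changes differed (adjusted p under 0.05, z test on the authors' fold changes with standard errors from q-values, Benjamini-Hochberg over the shared genes, chosen after the data were seen). In 28 of these both compounds moved the gene the same way, 25 of them more with brazilin. Several of the 25 are MTRNR2L genes, which resemble the same mitochondrial gene and may share reads, so they may not be separate signals. The authors' fold changes sit below the ratios of FPKM means by a median of 0.09 with brazilin and 0.008 with acetylated brazilin. The differences therefore depend in part on the scaling, and no other scaling was tried for this test. ITGA1 fell by 2.67 with brazilin and by 0.72 with acetylated brazilin (difference -1.95, interval -2.23 to -1.67), OLAH by 2.48 and 0.61, and ASB2, a ubiquitin ligase subunit gene, by 2.10 and 0.60. TRIML2 rose by 2.37 and 1.03 (difference 1.34, interval 1.02 to 1.66), and MTRNR2L8 fell by 2.16 and 0.98 (difference -1.18, interval -1.46 to -0.90). The 3 genes that moved more with acetylated brazilin were FTH1 (difference -0.67, interval -0.79 to -0.55), GCLM (-0.34, interval -0.52 to -0.17) and TXNIP (0.21, interval 0.07 to 0.35). The other 10 genes changed in opposite directions, and for these the z test adds nothing to their listing in both tables. PAK6 was listed at 0.01 FPKM in untreated cells and at 0.145 and 0.14 FPKM with the 2 compounds, with no usable difference (interval -5.96 to 5.30), and it shares sequence with the readthrough gene BUB1B-PAK6. For the other shared genes the intervals include 0 or the test did not pass, which does not show that the compounds act alike.

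**Figure D3:**
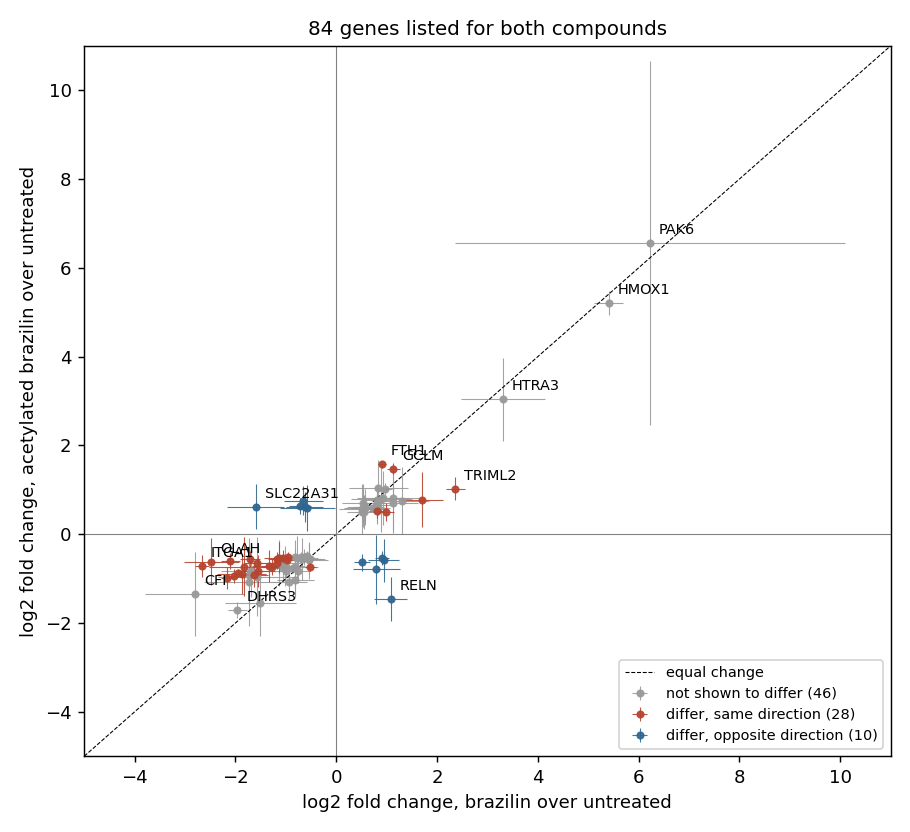
Log2 fold changes over untreated cells of the 84 genes listed for both brazilin (horizontal axis) and acetylated brazilin (vertical axis), from the authors' deposited tables. Bars are 95% intervals from the q-values, the dashed line marks equal change, red points differ in size (28 genes), blue points differ in direction (10 genes) and grey points were not shown to differ (46 genes). HMOX1 and HTRA3 lie near the line of equal change, and ITGA1 and OLAH lie further from 0 with brazilin.

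Brazilin and methylated brazilin shared CCL26, CST1, TXNIP, SOX4 and BEST1, all moved in the same direction by both. SOX4 fell by 2.20 with brazilin and by 0.75 with methylated brazilin (difference -1.45, interval -1.79 to -1.11, z test from the authors' q-values, adjusted p = 2.05e-16), and CST1 by 1.73 and 0.94 (difference -0.79, interval -1.22 to -0.36, adjusted p = 0.000745). Differences for CCL26 (0.36, interval -0.49 to 1.22), TXNIP (0.40, interval -0.01 to 0.81) and BEST1 (0.19, interval -0.81 to 1.19) were not detectable. Acetylated and methylated brazilin shared CCL26, TNFRSF9, CST1, TXNIP and GEM, all lower with both, and 0 of the 5 differed by the same z test, with 0 also at an unadjusted p under 0.05. The intervals of these differences reach from -0.77 to 0.81 for CST1 and from -0.22 to 0.59 for TXNIP, so differences of that size are not excluded. CCL26, CST1 and TXNIP were the 3 genes in all 3 tables. Of the acetylated brazilin genes 109 were not in the brazilin table, and 4 methylated brazilin genes, HSPA1A, KRT34, NQO1 and SLX1B, were in neither other table. Absence from a table means only that the gene missed the authors' criteria there, and the difference was not tested for such genes.

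The 3 comparisons used the same untreated samples, whose chance values push the fold changes of different compounds the same way. In simulated groups with no effect that shared their controls, 99.9% of genes past an unadjusted threshold in both had the same sign. A common sign alone therefore cannot show a common effect. For brazilin and acetylated brazilin the covariance of the shared genes' fold changes was 1.70. The estimate from shared controls, which leaves out the selection of genes, was 0.0415. Every shared gene changed by at least 0.5 with both compounds, and a common sign alone then raises the covariance. These values therefore cannot decide whether shared controls are the only source. For acetylated and methylated brazilin the values were 0.0214 and 0.0150 over 5 genes. All 5 were lower with both compounds, and a covariance leaves out that common fall, so it cannot decide here either. Every shared gene had passed the authors' criteria in both tables. Independent lists of the sizes for brazilin and acetylated brazilin would share 8.22 higher and 5.50 lower genes if 20056 genes had been tested, and 16.4 higher genes if 10028 had, the number tested being unknown. The controls could not be split between the comparisons because the tables hold no values per sample, so part of the excess may come from the shared controls.

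On the human assembly GRCh38.p14, HMOX1 (gene ID 3162) spans positions 35381096 to 35394207 of chromosome 22, FTH1 (2495) 61964285 to 61967634 of chromosome 11, ITGA1 (3672) 52787916 to 52959209 of chromosome 5, SOX4 (6659) 21593751 to 21598619 of chromosome 6 and DHRS3 (9249) 12567910 to 12618210 of chromosome 1. The values refer to whole genes, exons being the part that RNA sequencing of transcripts counts. Of the 18 listed members of the fixed histone list 16 lie on chromosome 6 and 2 on chromosome 1, and of all 30 histone genes in the brazilin table, by name, 20 lie on chromosome 6. H2BC4 (8347) spans 26113170 to 26123926 and H2BC12 (85236) 27138293 to 27146858 of chromosome 6.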

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

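The tests in this part were chosen after the fold changes had been seen. Each gene here changed in opposite directions with brazilin and with acetylated brazilin in the authors' deposited tables. Genes listed in opposite directions pass the z test on their difference by construction, so the intervals describe the size of the difference only. RELN, which encodes the matrix protein reelin, was higher with brazilin and lower with acetylated brazilin, at 0.545 FPKM untreated, 1.24 and 0.20 FPKM (difference 2.54, interval 1.95 to 3.13). TFPI2, a serine protease inhibitor gene, stood at 30.5, 61.0 and 21.1 FPKM (difference 1.46, interval 1.25 to 1.66). The regulators of G protein signalling RGS2 and RGS4 were both higher with brazilin and lower with acetylated brazilin, with differences of 1.53 (interval 0.95 to 2.11) and 1.59 (0.69 to 2.49). ATP5MK, a subunit gene of the mitochondrial ATP synthase, stood at 326.5, 427.5 and 171.5 FPKM (difference 1.14, interval 0.90 to 1.39). The remaining 5 were lower with brazilin and higher with acetylated brazilin. The transporter genes SLC22A18 and SLC22A31 differed by -1.23 (interval -1.72 to -0.73) and -2.22 (interval -2.97 to -1.46), SEL1L3 by -1.36 (interval -1.64 to -1.08), CCDC163 by -1.41 (interval -1.91 to -0.91) and TMEM8B by -1.17 (interval -1.93 to -0.42). All 10 kept these directions in the FPKM means. No explanation was tested for them.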

How the results depend on the processing

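The tests within length, GC, FPKM and copy settings, the FPKM-ratio scaling and the q-based error were chosen after the data were seen. No paired analysis was possible because the tables hold group means only. The planned settings on values per sample (other pseudocounts, leaving out a replicate, a replicate block, other size factors) were not run for the same reason. Stricter thresholds leave fewer genes by construction. With an absolute log2 fold change of at least 1 or 2, 810 and 225 genes were left for brazilin, 24 and 5 for acetylated brazilin, and 5 and 2 for methylated brazilin. With q under 0.001, 114 and 4 genes were left for acetylated and methylated brazilin. Shared genes with a change of at least 1 in both tables numbered 10, 1 and 1 for brazilin with acetylated, brazilin with methylated and acetylated with methylated brazilin. Among brazilin genes that changed by at least 1, only histones and the stress response of the 6 lists past the threshold had enough members to test, and the count past it was 1, the histones. The stress response list had an adjusted p there of 0.0591 (range over its settings 0.00189 to 0.0591), with fewer genes tested. Ribosome biogenesis had 0.0997 within classes of length and GC content (range 0.00164 to 0.0997), and the cause was not tested. Histones, mitosis, hypoxia and lipid synthesis stayed past the threshold in every setting that could test them, at no more than 0.0156, 0.0155, 0.0169 and 0.0402. For acetylated brazilin the count of lists past the threshold went from 0 to 1 with q under 0.001 and to 1 without near-identical copies. NF-kB genes ranged from 0.0297 to 0.296 and immediate early genes from 0.0464 to 0.173. Both passed with q under 0.001 and with at least 1 FPKM, and NF-kB genes also within classes of mean FPKM (0.0351). With the mean of both groups in place of the higher group, the median FPKM of brazilin genes was 4.54 in place of 5.93 for higher genes and 7.78 in place of 9.26 for lower genes. With a covariance for the shared controls 45 genes in place of 38 differed between brazilin and acetylated brazilin. With the ratio of FPKM means as the fold change, the share of higher genes among the listed brazilin genes went from 47.6% to 58.4%. The larger direction thus changed, but genes that would pass only by this ratio could not be counted. The sign was opposite for 6 brazilin genes. The depth is unknown, and 389 brazilin genes were under 1 FPKM in both groups.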

Other observations

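The gene groups of the first paragraph and the tests on S phase, on opposite copies and on length with GC content were chosen after the result was seen, and the other predictions were written before it. Among brazilin genes grouped by the first 3 letters of their symbol (56 groups of at least 7), all 10 MRP genes, which encode mitochondrial ribosomal proteins, were higher (log2 0.51 to 0.84, Fisher's exact test, adjusted p = 0.0113), and so were 13 of 14 POL genes, mostly subunits of RNA polymerases (adjusted p = 0.0113). Within 10 classes of transcript length these gave 0.235 and 0.0685. The 11 H2B histone genes were also all higher (Fisher's exact test, adjusted p = 0.0113), but this call was lost within length (0.157). The 8 MTR genes, which are MTR and the 7 MTRNR2L genes described below, were all lower (Fisher's exact test, adjusted p = 0.0576, and 0.00466 within length). The 7 MTRNR2L genes resemble the same mitochondrial gene and may share reads, so the test may count a single signal several times. All 8 IFT genes, which encode carriers of intraflagellar transport in cilia, were lower (log2 -0.94 to -0.51, adjusted p = 0.0576, and 0.0470 within length). All 8 SEC genes, among them SEC61A1 of the endoplasmic reticulum translocon (284 to 177 FPKM with brazilin), were lower (adjusted p = 0.0576, and 0.0685 within length). Of 18 genes that start with DNA, mainly DNAJ cochaperones and dynein genes, 16 were lower (adjusted p = 0.0216, and 0.0892 within length). All 30 histone genes in the brazilin table, by name and including variants outside the fixed list, were higher, also by FPKM means.

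The 7 listed MTRNR2L genes, nuclear genes that resemble the mitochondrial 16S ribosomal RNA gene (93.0% identity over 1302 nt for MTRNR2L8), all fell with brazilin, by 1.64 to 2.16 on the log2 scale. Of these, 6 also fell with acetylated brazilin, by 0.73 to 0.98. The mitochondrial gene itself was not analysed here, and whether its reads were counted for these genes was not tested.

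Long transcripts fell and short ones rose with brazilin. The median length was 4442 nt for lower and 2580 nt for higher genes, a ratio of 1.72 (two-sided permutation test, p = 2e-05, the smallest 100000 permutations can give), and 1.47 with acetylated brazilin (p = 0.00078), under the 1.5 set beforehand for a clear trend. The trend does not come from the fixed lists, since the ratio was 1.73 without their genes. For the lists, 6 of 6 stayed past the threshold within 10 classes of length and 5 of 6 within classes of length and GC content. That argues against length as the whole cause of the list directions, but does not exclude it as a part. GC content stays open, because 20.0% of genes in the lowest of 5 GC classes and 75.3% in the highest were higher, and the length ratio within GC classes was 1.18 at the lowest and 1.74 at the highest. A difference in RNA quality or library preparation may also be the cause and cannot be told apart from the treatment, as 0 libraries have values of their own in the tables, and a response of the cells to brazilin stays open too.

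The median rise of the 18 histone genes of the fixed list with brazilin was 2.57 larger on the log2 scale than that of listed genes that are not histones in the same range of transcript length (permutation p = 2e-05, the smallest possible), which argues against length as its whole cause. Among transcripts of 381 to 800 nt, 11 histone genes of the fixed list had a median of 3.04 and 39 genes that are not histones one of 0.58 (permutation test, p = 0.004). Replication-dependent histone transcripts lack a poly(A) tail, so a larger capture of such RNA is a candidate explanation, but 0 small RNA genes without a tail were in the brazilin table, which holds almost only protein-coding genes. A larger share of cells in S phase is another candidate. Of 43 fixed DNA replication genes 3 were listed as higher, by 0.54 to 0.56, and 0 as lower, too few to decide. None of them thus had a listed rise near the histone median of 3.14. Genes that missed the criteria have no values, so the question stays open. A change in the processing or synthesis of histone transcripts with brazilin was not tested.

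Several very large fold changes belong to genes at 0.01 FPKM in 1 group. Over the 3 tables, 59 entries of this kind could be searched for copies, and 30.5% of them had a coding copy of at least 98% identity, against 3.49% of 3008 other entries searched (two-sided Fisher's exact test, p = 3.38e-12). With each gene counted once, a count added after the result was seen, 17 of 58 genes had one against 96 of 2919 (Fisher's exact test, p = 1.14e-11), which suggests that reads divided between copies may produce part of these calls, but most such genes have no copy of that kind. In 5 pairs of copies 1 member was higher and the other lower in the same table. In 2 of the 5 the summed FPKM changed by under 0.5 on the log2 scale, H4C12 with H4C11 (-0.06) and MAGED4 with MAGED4B (0.29), both with acetylated brazilin. The sums of HBA1 with HBA2 (2.42), GOLGA6A with GOLGA6C (-0.65) and C4A with C4B (-0.70) moved more with brazilin, at under 5 FPKM and with no known error.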
